A study of Mus musculus with 2 samples.

How the data were processed

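RNA sequencing of mouse lung fibroblasts gave 2 libraries, 1 labelled IR and 1 labelled NC, made from total RNA after removal of ribosomal RNA. Per the submitters' processing notes, the tools used were cutadapt 1.9.3, HISAT2, HTSeq 0.9.1 and edgeR with the mouse genome build mm10. The notes do not say which release of the gene annotation was used, nor whether the counting took account of strand. Named genes that overlap another gene on either strand over at least 10% of their exon sequence are therefore marked as uncertain. The labels' protocols describe centrifugation and filtration of culture supernatants before library construction, while the labels name fibroblasts as the source. Whether the RNA came from cells or from vesicles is not stated.

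The deposited table holds raw read counts per gene and library, per the file headers, for 14694 genes. All of them carry the protein-coding biotype and at least 1 read in 1 of the libraries. A further 2 value columns of the table were not used here. Gene symbols and pathway assignments were taken from the table. Gene positions, transcript lengths, GC contents and exon overlaps came from GENCODE vM21 on GRCm38, which held 14584 of the 14694 gene identifiers (99.2%).

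The libraries held 35219511 (IR) and 36084512 (NC) counted reads. Library sizes were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 0.991 for IR and 1.01 for NC. The log2 ratio of IR over NC was computed from log2 CPM (read counts scaled to a common library size) with a prior count of 2, for the 10921 genes with at least 50 reads summed over both libraries. Each ratio has an exact 95% interval (Clopper-Pearson, from the binomial split of a gene's reads between the libraries). A gene was called at least 2-fold higher or lower when its absolute log2 ratio was at least 1 and this interval excluded a ratio of 1. CPM values have exact Poisson intervals. All such intervals, and the floor of 3 counts per library (0.086 CPM in IR and 0.0824 CPM in NC), cover counting error only. Reads amplified by PCR are not independent molecules, so the intervals may be too narrow even for that error. With 1 library per group there is no replicate check, and no p-value was computed across genes.

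The median log2 ratio was computed for gene lists covering fibroblast and myofibroblast genes, matrix, signalling, metabolism, stress, cell cycle, RNA modification, translation and markers of lung cell types. There were 47 lists, and the 38 with at least 5 compared members were each set against 10000 random lists of the same size drawn from genes in the same decile of mean expression. A median was described as standing apart when its percentile was below 2.5 or above 97.5, limits set after the medians had been seen. The interval of a median is the 95% binomial interval of order statistics over the members. With 5 members, too few for that level, it is the range from lowest to highest. It treats members as independent, which co-regulated genes are not. The gene lists, the rule for a 2-fold difference, the alternatives not said to be added and the rule for naming genes were written before the data were examined.

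The genes named are Pfkfb3, Mettl1, Wdr4, Acta2, Col1a1, Col3a1, Fn1, Tgfb1 and Cdkn1a. To these were added the 12 genes with the highest and the 12 with the lowest log2 ratio among those called, with at least 200 reads over both libraries and a symbol that is no clone or model name. From each list described, up to 2 members with the highest and 2 with the lowest ratio were named, as were the 5 most abundant genes of each library. Genes outside this rule are said to have been chosen after their values were seen.

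The procedure was tested on simulated counts for the comparison of IR with NC, with counting noise only and 200 changed genes among 14694, of which 10931 were compared. It found 100% of the genes changed 4-fold and 100% of those changed 3-fold, and it called 1 of 10731 unchanged genes. The changed genes were drawn from those with at least 200 reads over both libraries. Detection at lower counts, and of changes nearer to 2-fold, was therefore not tested. The intervals covered the true ratio for 95.5% of the unchanged genes. Such data hold no biological variation, so the simulation says nothing about differences between cultures.

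The alternatives were other scalings (total counts, the size factors of DESeq2 1.42.0, upper quartile, and totals without mitochondrial genes and the 20 most abundant genes), prior counts of 0.5 and 5, no filter and a filter of 200 reads, thinning of the deeper library, centring on the trend over expression, fold rules of 1.5 and 4, means in place of medians and random lists matched on length. Those added after the data were seen were centring on a loess trend (span 0.5) over transcript length and GC content, leaving out genes with exon overlap, and random lists matched also on GC content. Sequence shared between genes was measured as the percent of a gene's 50-base words that occur in transcripts of other annotated genes. Figures were drawn with matplotlib 3.10.9.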

Results

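RNA with mouse lung fibroblasts as its labelled source, from cells or vesicles (not stated), was sequenced after depletion of ribosomal RNA. There was 1 library labelled IR and 1 labelled NC. Both carry the number 4, and the labels spell out neither the group names nor the number. Directions below are therefore given between the library labelled IR and the library labelled NC. The series concerns radiation-induced lung fibrosis and the turning of fibroblasts into contractile, matrix-depositing myofibroblasts, with PFKFB3 and the methylation of tRNA at m7G as its molecular subjects. The comparison addresses which mRNAs differ between these 2 libraries. Each group has 1 library, so no difference has a replicate check, and each statement compares these libraries and not the conditions.

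The libraries were close in depth, with 35219511 counted reads for IR and 36084512 for NC. Reads fell on 13902 genes in IR and 13954 in NC. The 5 most abundant genes were the same in both: Lgals1 (galectin-1), Eef2 (a translation elongation factor), Rplp0 (a ribosomal stalk protein), Ftl1 (ferritin light chain) and Pkm (pyruvate kinase). Together they took 4.40% of the IR reads and 4.00% of the NC reads. Their log2 ratios of IR over NC lay between 0.07 for Eef2 and 0.22 for Pkm. Ftl1 shares 90.6% of its 50-base words with other genes, Rplp0 41.8% and Pkm 34.4%, so their reads may be split among copies. Ribosomal protein genes made up 12.5% of the IR reads and 11.9% of the NC reads, and the mitochondrial genome 0.0421% and 0.071%, from the 5 of its 13 protein-coding genes that the table lists.

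The list of fibroblast markers had the largest sum among the cell type lists, carried by a few genes that other cells also express. Of its 22 markers 16 were in the table, and they summed to 5491 CPM in IR (95% Poisson interval 5467 to 5516) and 5020 CPM in NC (4997 to 5043), with Vim (vimentin, chosen after its value was seen) giving 40.0% and 36.3% of these reads. The median over the 22 markers was 1.15 CPM in IR and 1.19 CPM in NC. Without Vim and S100a4 the sum was 2617 CPM in IR and 2792 CPM in NC, which turns the order of the libraries. General epithelial markers reached 6.39 CPM in IR (5.58 to 7.29) and 3.84 CPM in NC (3.23 to 4.54), and haemoglobin and other erythroid markers 0.344 and 0.275 CPM. Lymphocyte markers summed to 15.9 and 19.3 CPM, almost all from Lck, and neutrophil and mast cell markers to 17.8 and 18.2 CPM, almost all from S100a8. Macrophage markers summed to 125 CPM in IR (121 to 129) and 131 CPM in NC (128 to 135), endothelial markers to 79.1 and 85.6 CPM, and smooth muscle and pericyte markers to 92.9 and 88.7 CPM. Mesothelial markers summed to 100.3 CPM in IR (97.0 to 104) and 199 CPM in NC (194 to 204). Msln (mesothelin, a surface protein of mesothelial cells) supplied 97.3% and 99.1% of those reads. Alveolar epithelial markers summed to 1205 CPM in IR and 1190 CPM in NC. Pdpn supplied 56.0% and 48.3% of these reads, and the other alveolar markers summed to 531 CPM in IR and 615 CPM in NC. The median over the 17 alveolar markers was 0.0287 CPM in IR and 0.0549 CPM in NC, so a few genes carried these sums. Sftpc, the surfactant gene of alveolar type II cells and chosen after its value was seen, had 0 and 2 reads. Airway markers summed to 574 and 498.5 CPM, of which Tubb4b, a tubulin gene that other cells also express, supplied 99.8% and 99.7%.

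Among the 10921 genes compared, 175 were at least 2-fold higher and 199 at least 2-fold lower in the IR library. The expression of the libraries was otherwise close: 96.6% of the genes lay within 2-fold and 86.6% within 1.5-fold, and Pearson's r of log2 CPM was 0.985 across genes, which are not independent replicates. The counting interval lay above a ratio of 1 for 3402 genes and below 1 for 3543. The median absolute deviation of the log2 ratio was 0.62 among the 20% of genes with the lowest expression and 0.25 among the 20% with the highest. It was scaled to equal the standard deviation for normally distributed values. Log2 ratios declined with transcript length (Spearman's rho across genes -0.124), from a median of 0.10 in the shortest 10% of genes to -0.09 in the longest 10%.

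**Figure D1:**
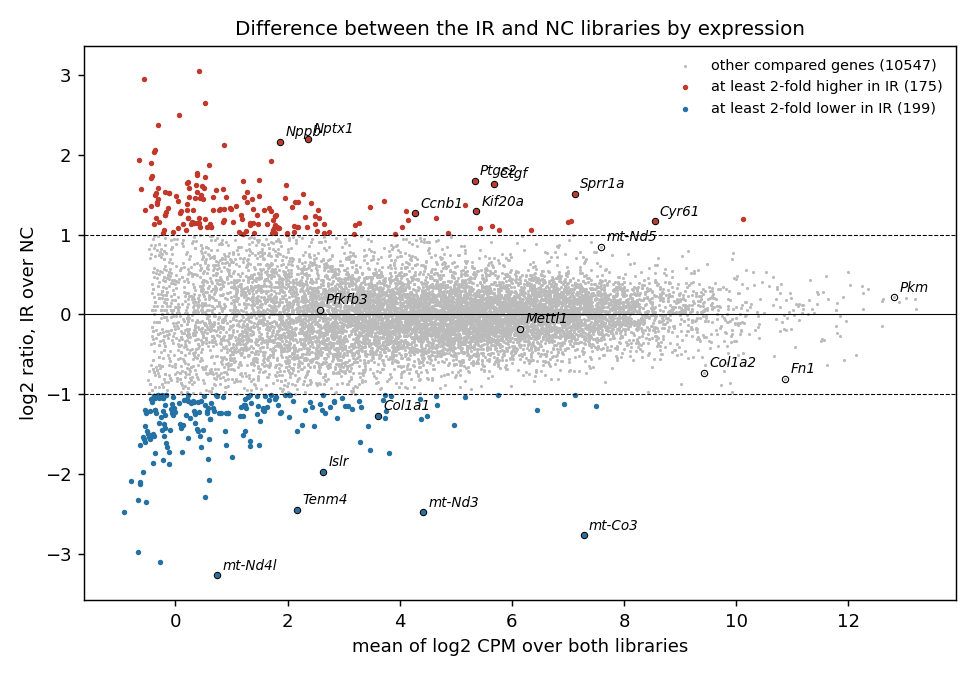
Log2 ratio of IR over NC against the mean log2 CPM of both libraries, 1 point per compared gene. The 175 genes at least 2-fold higher in IR (red) and the 199 at least 2-fold lower (blue) lie mostly at low expression, and dashed lines mark 2-fold differences.

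The genes named by the series differed little. Pfkfb3, which encodes the enzyme that makes the phosphofructokinase activator fructose-2,6-bisphosphate, had 212 reads in IR and 212 in NC (log2 ratio 0.06, 95% counting interval -0.22 to 0.34). It lies on chromosome 2 at 11471433 to 11554077 (GRCm38). Mettl1, the catalytic subunit of the m7G tRNA methyltransferase, had 2324 and 2743 reads (log2 ratio -0.18, interval -0.26 to -0.10), and its partner Wdr4 had 3291 and 2931 reads (0.23, interval 0.16 to 0.30). Across the 11 compared m7G writers and related cap or rRNA methyltransferases and readers the median was 0.09, at percentile 82.5 of the random lists. Rnmt, the mRNA cap methyltransferase, was the highest of them (0.80), followed by the cap-binding Eif4e (0.39), while Fam103a1 and the scavenger decapping enzyme Dcps were the lowest (both -0.27). Glycolytic genes had a median of -0.04 (percentile 22.1) with 11 of 23 ratios above 1 and none 2-fold different. Pfkfb1 (0.63, from 53 and 35 reads) and Pfkp (0.36) were highest in that list, and the phosphofructokinase Pfkl (-0.43) and the pyruvate dehydrogenase kinase Pdk1 (-0.50) lowest.

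Enzymes that modify tRNA at other positions had a median of 0.23 (percentile 99.7, interval over members -0.0041 to 0.45), with 17 of 25 ratios above 1. Nsun3, a mitochondrial tRNA cytosine methyltransferase, had a log2 ratio of 0.998 from 111 and 57 reads, just under the 2-fold limit, and the methylthiotransferase Cdkal1 one of 0.74. Thg1l (-0.40) and Nsun2 (-0.42), which overlaps other genes over 11.1% of its exon sequence, were lowest. Aminoacyl-tRNA synthetases had a median of 0.15 (percentile 96.1, and 99.1 with matching on length), led by Farsb (0.86) and Rars (0.65), with Wars (-0.18) and Mars (-0.32) lowest. Lysine acetyltransferases, deacetylases and acetyl-CoA enzymes, the class of genes behind protein acetylation, had a median of 0.05 (percentile 73.8). Sirt1 (0.57) and Kat8 (0.43) were highest there, and Ep300 (-0.38) and the acetyl-CoA synthetase Acss2 (-0.48) lowest.

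Of the 15 compared matrix genes of fibroblasts, 9 were lower in the IR library and 6 higher, each with a counting interval that excluded a ratio of 1. Fn1 (fibronectin) had 49419 reads in IR and 90065 in NC (log2 ratio -0.80, interval -0.82 to -0.79). Col1a1 (the alpha1 chain of type I collagen, chromosome 11, 94936224 to 94953042) had 273 and 688 reads (-1.27, interval -1.48 to -1.07), and Col6a3 613 and 1298 reads (-1.02). Col1a2, the partner chain of Col1a1 and chosen after its value was seen, had 18761 and 32428 reads (-0.73). It reached 538 CPM in IR and 890 CPM in NC, against 7.83 and 18.9 CPM for Col1a1. The cause of this imbalance was not tested. Col3a1 differed less (565 and 690 reads, -0.23, interval -0.39 to -0.06). Tnc (tenascin-C, a matrix protein made during repair) went the other way, with 745 and 290 reads (1.42, interval 1.23 to 1.62), and Fbn1 (fibrillin-1) had a ratio of 0.78. The 15 collagens and other matrix genes had a median of -0.21 (interval over members -0.73 to 0.24), at percentile 1.22 of random lists matched on expression and 4.24 of lists matched also on transcript length, or 13.025 with GC content matched too. Lung fibroblast markers, which share collagen genes with that list, had a median of -0.38 (percentile 0.05, interval over members -0.73 to 0.27). Inmt (indolethylamine methyltransferase) was among the lowest markers at -1.21, while Gsn (gelsolin) reached 0.37 and S100a4, which overlaps another gene over 51.7% of its exon sequence, 0.74.

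Contractile genes of myofibroblasts did not stand apart as a list, with a median of 0.17 (percentile 95.2) and 12 of 15 ratios above 1. Acta2 (alpha smooth muscle actin) was scarce in both libraries, with 67 reads in IR and 38 in NC (log2 ratio 0.85, interval 0.29 to 1.49). Tagln (transgelin) had 175 and 71 reads (1.34), but 67.9% of its exon sequence overlaps other genes. The lowest members were Flna (-0.19) and Mylk (-0.28). Tgfb1 had 3861 and 3443 reads (0.23, interval 0.16 to 0.29). The TGF-beta response list had a median of 0.07 (percentile 78.6) with members at both ends. Ctgf (connective tissue growth factor, chromosome 10, 24595442 to 24598683) had 3147 and 1054 reads (1.64, interval 1.54 to 1.74), though 23.2% of its exon sequence overlaps another gene. Id3, a transcriptional inhibitor, had a ratio of 1.16, Ltbp3 one of -0.66 and the TGF-beta antagonist Pmepa1 one of -0.87. The list of YAP and TAZ targets had a median of 0.04 (percentile 66.8), with 3 of 14 genes at least 2-fold higher: Ctgf, Nt5e (1.52, from 53 and 18 reads) and, chosen after its value was seen, Cyr61 (1.17). Arhgef17 (-0.43) and Foxf2 (-0.17) were lowest. Matrix crosslinking and turnover enzymes had a median of -0.07 (percentile 17.2) but a mean of 0.10, with the stromelysin Mmp10 at 2.38 from 63 and 11 reads, Loxl4 at 0.54, Mmp14 at -0.29 and Loxl3 at -0.30.

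Genes of G2 phase and mitosis were higher in the IR library throughout the list. All 24 log2 ratios were above 0, for 23 genes with the counting interval above 0 as well, and the median was 0.73 (interval over members 0.51 to 0.98), above all 10000 random lists. The hyaluronan-mediated motility receptor Hmmr (133 and 49 reads, 1.47) and the mitotic kinesin Kif20a (2243 and 955 reads, 1.29) were highest, Kif20a with 29.3% of its exon sequence overlapping another gene. The other members at least 2-fold higher, chosen after their values were seen, were Ccnb1 (1.27), Ccnb2 (1.11) and Tpx2 (1.08). Cdk1 (0.17) and Aurkb (0.10) were lowest. DNA replication genes had a median of 0.05 (percentile 69.5), with Cdc6 (0.71) and Rrm2 (0.53) highest and Fen1 (-0.12) and Ccne2 (-0.52) lowest. The 5 compared replication-dependent histone genes had a median of 0.52 (percentile 98, interval over members -0.18 to 1.57). Hist1h4d (1.57, from 38 and 12 reads) and Hist1h1e (0.78) were highest and Hist1h2bc (0.32) and Hist1h1c (-0.18) lowest among them, and near-identical histone copies make these values uncertain.

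Targets of p53, the transcription factor activated by DNA damage, had a median of 0.09 (percentile 88.4). Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, had 45774 reads in IR and 37825 in NC (log2 ratio 0.34, interval 0.32 to 0.36). Plk2 (0.70) and Plk3 (0.65) were highest, and Sesn1 (-0.34) and Trp53inp1 (-0.73) lowest. Genes of double-strand break signalling and repair had a median of 0.12 (percentile 91.6), from Lig4 (0.87, 63 and 35 reads) and Xrcc4 (0.74, 35 and 21 reads) to Mdc1 (-0.22) and Parp1 (-0.23). Neither list had a member 2-fold different.

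Immediate early genes, which growth factors and stress switch on within minutes, had a median of 0.38 (interval over members -0.02 to 0.70), above all 10000 random lists, with 16 of 22 ratios above 1. The transcription factors Egr2 (0.98) and Nr4a1 (0.97) were highest, and Dusp6 (-0.43) and Klf2 (-0.76) went the other way. NF-kappaB pathway and feedback genes had a median of 0.19 (percentile 97.9, interval over members -0.11 to 0.54) with 11 of 17 ratios above 1, and matching the random lists on transcript length and GC content as well put it at 97.0, no longer standing apart. Ptgs2 (cyclooxygenase-2) had 2518 reads in IR and 822 in NC (1.68, interval 1.56 to 1.79) and the adhesion molecule Vcam1 221 and 83 reads (1.45), while Bcl3 (-0.24) and Zc3h12a (-0.31) were lowest. Secreted factors of senescent and inflamed cells had a median of 0.18 (percentile 95.3). The cytokine Csf2 (85 and 14 reads, 2.5) and the chemokine Ccl20 (106 and 36 reads, 1.57) led that list, and Vegfa (-0.41) and Igfbp4 (-0.63) ended it. Interferon-stimulated genes had a median of -0.09 (percentile 5.84), with Cxcl10 (0.53) and Parp14 (0.47) highest and Zbp1 (-0.33) and Stat2 (-0.49) lowest.

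Cholesterol synthesis genes under the transcription factor SREBP2 were higher in the IR library, with 17 of 19 ratios above 1 and a median of 0.45 (interval over members 0.25 to 0.69), above all 10000 random lists. Sc5d (837 and 453 reads, 0.95) and the lanosterol synthase Lss (2342 and 1308 reads, 0.90) were highest, and Cyp51 (-0.0044) and Idi1 (-0.015) lowest. Nuclear genes of the respiratory chain had a median of 0.24 (percentile 99.9, interval over members 0.04 to 0.32), led by Cox7a2 (0.78) and Uqcrc1 (0.46), with Ndufa2 (-0.24) and Uqcrc2 (-0.47) lowest. The tricarboxylic acid cycle list had a median of -0.0016 (percentile 41.0), with Sdha (0.31) and Cs (0.24) highest and Dld (-0.52) and Fh1 (-0.74) lowest. Hypoxia-inducible genes were lower in the IR library, with 16 of 19 ratios below 1, a median of -0.32 (interval over members -0.64 to -0.18) and 1 of 10000 random lists lower. The mitophagy receptor Bnip3 (529 and 974 reads, -0.82) and Ankrd37 (147 and 284 reads, -0.88) were lowest, both overlapping other genes over more than 20% of their exon sequence, and the histone demethylase Kdm3a (0.45) and Ndrg1 (0.16) highest.

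**Figure D2:**
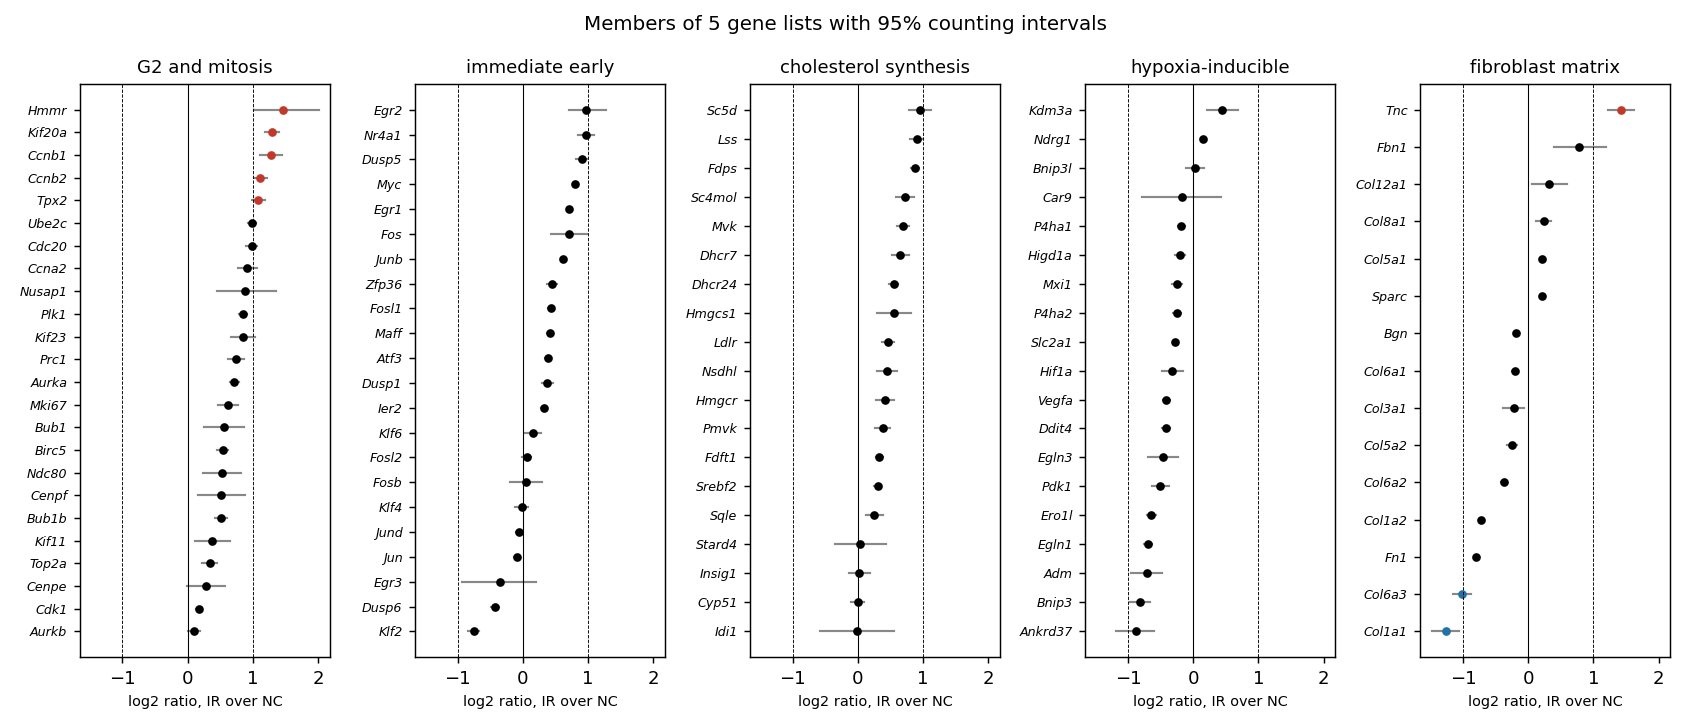
Log2 ratio of IR over NC for each compared member of 5 gene lists, with 95% counting intervals as bars, red or blue points for genes at least 2-fold higher or lower in IR and dashed lines at 2-fold. All 24 genes of G2 and mitosis lie above 0, and 16 of 19 hypoxia-inducible genes lie below it.

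The 5 measured genes of the mitochondrial genome diverged from each other. The respiratory chain genes mt-Co3 (2078 reads in IR and 14730 in NC, log2 ratio -2.76, interval -2.83 to -2.70), mt-Nd3 (313 and 1829 reads, -2.48) and mt-Nd4l (17 and 188 reads, -3.26) were lower in the IR library. In contrast mt-Nd4 had a ratio of -0.03 (interval -0.10 to 0.04) and mt-Nd5 one of 0.85 (interval 0.80 to 0.90). The list's median was -2.48 (interval over members -3.26 to 0.85), below all 10000 random lists. Copies of mitochondrial sequence elsewhere in the annotation share 99.9% of the 50-base words of mt-Co3, 98.0% of those of mt-Nd3 and 98.8% of those of mt-Nd4l, so these 3 values are uncertain.

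The remaining stress and translation lists did not stand apart from random lists matched on expression. Targets of the integrated stress response had a median of 0.015 (percentile 38.3), from Ddit3 (0.45) and Stc2 (0.23) to Vldlr (-0.49) and the cystine transporter Slc7a11 (-0.64). Endoplasmic reticulum chaperones and the unfolded protein response had one of -0.12 (percentile 3.88, and 2.39 with matching on length and GC content, past the limit of 2.5), from Atf6 (0.71) and Dnajb9 (0.39) to Pdia6 (-0.53) and Sel1l (-0.62). Cytosolic heat shock genes had one of 0.0076 (percentile 46.7), from Hspb1 (0.88, 79 and 44 reads) and Hsp90aa1 (0.60) to Dnaja1 (-0.25) and Hspa8 (-0.49). NRF2 targets and antioxidant enzymes had one of 0.0048 (percentile 45.0), from Nqo1 (0.66) and Hmox1 (0.58) to Mgst1 (-0.50) and, as in the stress response list, Slc7a11. Proteins of the large ribosomal subunit had a median of 0.07 (percentile 67.1), with Rpl6 (0.45) and Rpl18 (0.43) highest and Rpl4 (-0.44) and Rpl5 (-0.88, sharing 93.8% of its 50-base words with other genes) lowest. Those of the small subunit had one of 0.04 (percentile 48.7), with Rps14 (0.35) and Rps2 (0.32) highest and Rps6 (-0.39) and Rps24 (-0.41) lowest. Translation initiation and elongation factors had one of 0.03 (percentile 50.4), from Eif3c (0.50) and Eif5a (0.48) to Eef1b2 (-0.33) and Eif4a2 (-0.33).

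Extracellular vesicle markers and biogenesis genes had a median of -0.0156 (percentile 33.7). Rab27a, a GTPase of vesicle release, had 51 reads in IR and 121 in NC (log2 ratio -1.15, interval -1.69 to -0.70), and the tetraspanins Cd9 (0.49) and Cd81 (-0.42) went opposite ways, with Rab27b at 0.50 from 36 and 26 reads. Growth factor signalling genes, of the FGF, PDGF, IGF, EGF, HGF, Wnt and Hedgehog pathways, had a median of -0.18 (percentile 9.74), which was 0.29 when genes with exon overlap were left out, from Fgf10 (0.82) and Igf1r (0.51) to Axin2 (-0.75) and Fgf2 (-0.79, 23 and 43 reads). Lipid-storing fibroblast and adipocyte markers had one of -0.16 (percentile 15.7), with Fabp5 (0.77) highest, then Plin4 (-0.12), and Plin2 (-0.21) and Lipe (-0.33) lowest. Alveolar markers had one of -0.14 (percentile 14.8), from Aqp5 (0.28) and Pdpn (0.23) to Hopx (-0.64) and Napsa (-1.09). Endothelial markers had one of -0.12 (percentile 31.1), from Ramp2 (1.70, 45 and 13 reads) and Kdr (1.28, 47 and 19 reads) to Flt1 (-0.40) and Vwf (-0.43). Smooth muscle and pericyte markers had one of 0.02 (percentile 61.0), from Cspg4 (0.73) and Mcam (0.28) to Des (-0.12) and Notch3 (-0.19).

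**Figure D3:**
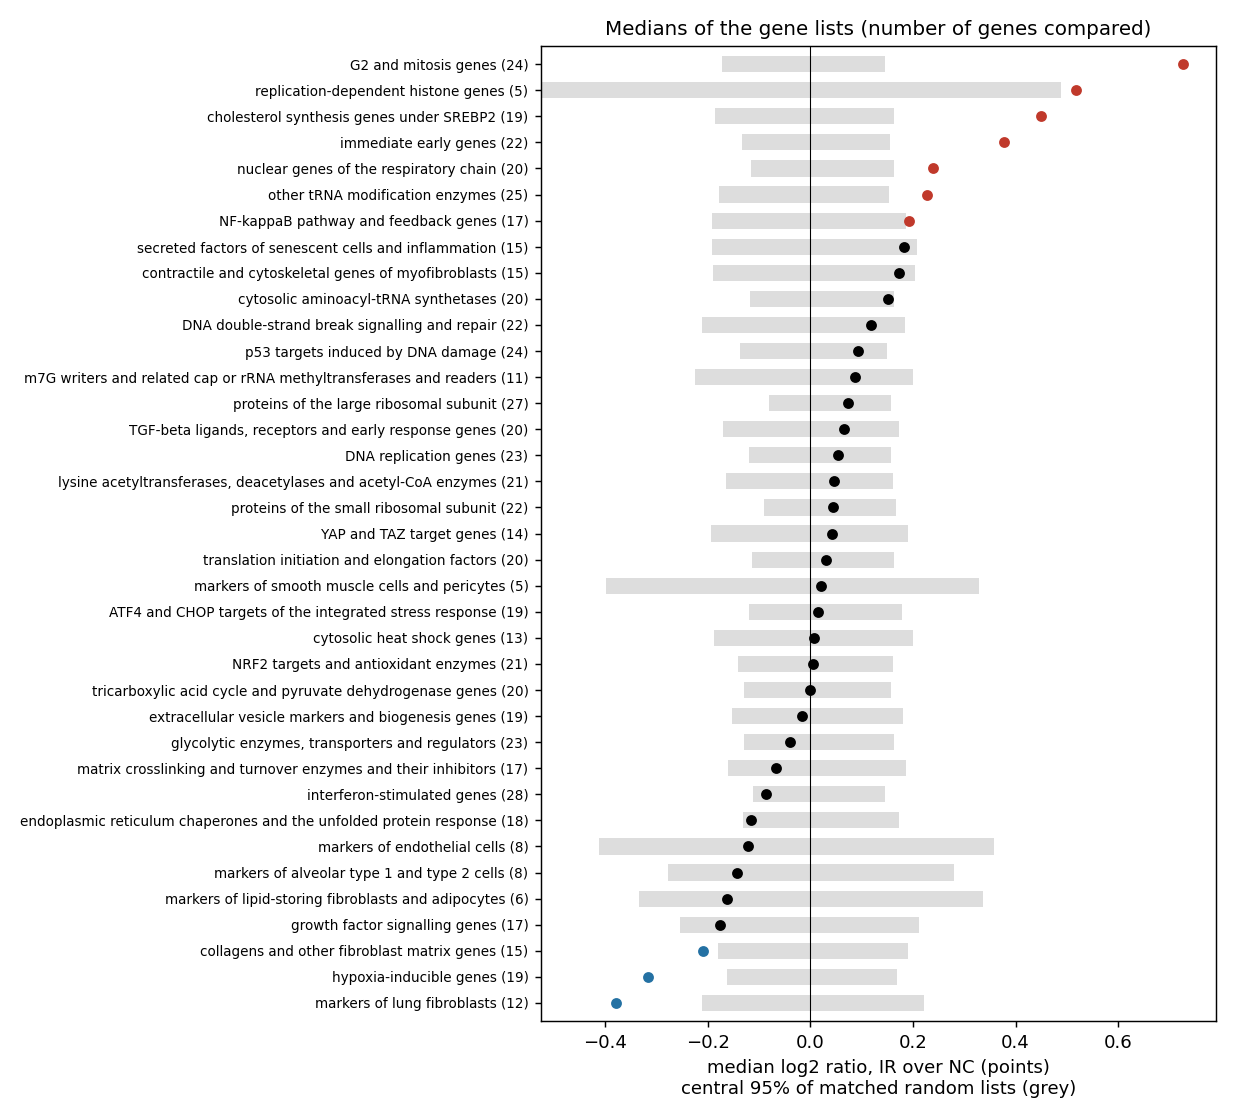
Median log2 ratio of IR over NC for each gene list with at least 5 compared members (points), with the central 95% of the medians of 10000 random lists matched on expression as grey bars. Red points lie above and blue points below that range, and the mitochondrial genome list, at -2.48, is left off the axis.

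Of the 38 lists, 11 lay outside the central 95% of their random lists, 7 above and 4 below. The expected number is 1.9 if members of a list vary independently of each other, as in the random lists. Members of a list can be co-regulated, which can place more lists outside. Lists also share members, so they are not independent. General epithelial (2 compared genes), airway (2), mesothelial (2), macrophage (3), lymphocyte (1), neutrophil and mast cell (1) and erythroid (0) markers had too few compared genes for a percentile. Msln was lower in IR at -1.01, and among macrophage markers Cd68 had a ratio of 0.47, Lyz2 -0.60 and Cd14 -0.80. The general epithelial genes were Elf3 (0.74) and Krt19 (0.50), the airway genes Tubb4b (0.21) and Cyp2f2 (-0.69), the lymphocyte gene Lck (-0.31) and the neutrophil gene S100a8 (-0.04). The table listed 0 of the sex-linked transcripts and 0 of the small non-coding RNAs.

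The largest ratios outside the lists came from genes of diverse function. Higher in the IR library were Nptx1 (neuronal pentraxin, 386 and 86 reads, log2 ratio 2.20, interval 1.89 to 2.58), the natriuretic peptide gene Nppb (269 and 61 reads, 2.17), the imprinted growth regulator Phlda2 (1.92), Lrr1 (1.62), the cornified envelope gene Sprr1a (8231 and 3006 reads, 1.52), the apoptosis gene Bok (1.51), Baalc (1.49) and Cnksr1 (1.45). Hist1h2ap (1.69) shares 93.1% of its 50-base words with other histone genes. Lower were the adhesion receptor Tenm4 (65 and 379 reads, -2.45, interval -2.88 to -2.10), the mesenchymal gene Islr (108 and 447 reads, -1.97), the ATP-gated channel P2rx3 (266 and 933 reads, -1.74), the secreted carbonic anhydrase Car6 (-1.70), Triqk (-1.64), Ppp2r3a (-1.64), Pdgfrl (-1.58) and the polyamine-degrading enzyme Sat1 (-1.46). Pgk1-rs7 (-1.59) shares 100% of its 50-base words with other genes, Pgk1 among them, so its reads cannot be assigned to it. The values of Bnip3, Fam103a1, Fen1, Hsp90aa1, Hspa8, Hspb1, Ramp2, Rpl6, Rps2, Rps6, S100a4, Tubb4b and mt-Nd4 are uncertain for the same reason, since each shares between 51.6% (Hspb1) and 81.2% (Fen1) of these words with other genes. Overlap with another gene over 10% or more of the exon sequence also makes the values of Hopx (27.2%), Fbn1 (20.1%), Uqcrc2 (19.7%), Napsa (18.9%), Ccne2 (17.4%), Lipe (15.6%), Cyp2f2 (13.5%), Eif4a2 (13.3%), Fgf2 (13.2%), Csf2 (12%), Loxl3 (11.6%), Ndufa2 (11.5%), Ddit3 (10.9%), Dnaja1 (10.8%), Wdr4 (10.8%) and Cd9 (10.7%) uncertain.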

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

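The alternatives chosen after the data were seen were centring on the trend over transcript length and GC content, leaving out genes with exon overlap, and random lists matched on length and GC content. No median of a list standing apart and no named gene past the 2-fold rule changed sign under the alternatives run. Medians close to 0, such as those of the TGF-beta response, YAP target, glycolytic, ribosomal and stress lists, changed sign under some of them while staying within their intervals, so they carry no direction.

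Counts of genes depended on the filter and the fold rule by construction. In place of 175 higher and 199 lower genes, no filter on low counts gave 584 and 606, a filter of 200 reads 73 and 71, genes without exon overlap 106 and 124, a 1.5-fold rule 665 and 754, and a 4-fold rule 10 and 14. Under the other alternatives both counts stayed within 1.5 times, and the scalings moved the median of all genes by at most 0.0274 on the log2 scale.

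The matrix gene list moved from percentile 1.22 to 4.24 with length matching and to 13 with length and GC matching, which takes it inside the limits. With length and GC matching the NF-kappaB list moved from 97.9 to 97.0, and the endoplasmic reticulum chaperones moved from 3.88 to 2.39. The aminoacyl-tRNA synthetases moved from 96.1 to 99.1 with length matching and 97.8 with length and GC matching. The cause was not tested for these 3. The remaining lists stayed on their side of the limits.

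The mean of the matrix crosslinking and turnover list was 0.10 against a median of -0.07, since Mmp10 alone had 2.38. Without overlapping genes the median of growth factor signalling was 0.29 in place of -0.18, and the cause was not tested. Scaling by total counts moved the fibroblast marker sums to 5439 CPM in IR and 5068 CPM in NC. It moved the contractile sums to 3057 and 3067 CPM (3086 and 3038 before), which changes their order. The alveolar sum of NC moved to 1201 CPM, while that of IR stayed within its interval of 1193.6 to 1216.6 CPM. The order of the alveolar sums therefore depends on the scaling too. Ratios of single named genes moved beyond their counting interval in 126 cases and stayed within it in 2041.

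Depth limits the scarce genes: Acta2, with 67 and 38 reads, has an interval of 0.29 to 1.49. No paired analysis was possible because each group has 1 library. The deposited table gives no fold changes or p-values to set beside these ratios, and restricting it to protein-coding genes would remove none, so neither comparison was run.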

Other observations

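The pathway values, and all tests here except the measure of sequence shared between the mitochondrial genes and their copies, were chosen after the results had been seen. For that measure, the comparison of mt-Co3, mt-Nd3 and mt-Nd4l with mt-Nd4 and mt-Nd5 was framed with their ratios known. None of the patterns has a replicate check, so variation between cultures stays an open explanation for each of them, as does the group difference itself, which was not tested. Explanations below that concern cells assume that the RNA came from cells, which the labels do not state.

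The pathway assignments of the deposited table gave 245 pathways with at least 15 compared genes. Of these, 19 lay above and 18 below the central 95% of 2000 random lists each. The expected number outside is 12.25 if genes of a pathway vary independently of each other, which co-regulated genes do not. Pathways also share genes, so they are not independent. Allograft rejection and graft-versus-host disease, for example, each had 16 compared genes and a median of -0.2957. Lysosome genes had a median log2 ratio of -0.13 in the IR library, with 74 of 106 ratios below 1. The genes named for this pathway and the next were chosen after their values were seen. Psap (prosaposin) had 88202 reads in IR and 142310 in NC (-0.63), Gaa (acid alpha-glucosidase) -0.71, Lamp1 -0.41 and Ctsd (cathepsin D, overlapping another gene over 34.4% of its exon sequence) -0.27. Antigen processing and presentation had a median of -0.18, with 31 of 44 ratios below 1. The abundant MHC class I genes H2-K1 (131965 and 196075 reads, -0.51) and H2-D1 (111486 and 173286 reads, -0.57) and their light chain B2m (-0.15) were all lower, although H2 genes resemble each other in sequence, so reads of 1 can be counted for another. The percentile of this pathway was 0 with and without matching on length and GC content. Ribosome biogenesis had a median of 0.16 with 51 of 68 ratios above 1, RNA polymerase subunits 0.20 with 22 of 27, and oxidative phosphorylation 0.19 with 71 of 97. The ECM-receptor interaction pathway had a median of -0.18, and its percentile moved from 0 to 5.3 when random lists were matched on length and GC content. The ribosome pathway likewise moved from 99.5 to 73.2.

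Within the mitochondrial genome, mt-Co3, mt-Nd3 and mt-Nd4l were lower in the IR library (log2 ratios -2.76, -2.48 and -3.26) while mt-Nd4 (-0.03) and mt-Nd5 (0.85) were not. A lower amount of mitochondrial RNA as a whole would lower all 5, which does not describe the ratio of 0.85 for mt-Nd5 (interval 0.80 to 0.90). That ratio is part of the pattern itself, so this is no separate test. It rests on 1 gene, and its interval covers counting error only. A loss of short transcripts is argued against by the 215 nuclear genes with transcripts of at most 784 bases, whose median was 0.094 (interval 0.06 to 0.17). The 3 lower genes share at least 98.0% of their 50-base words with other annotated genes, against 62.2% for mt-Nd4 and 7.61% for mt-Nd5, so reads assigned differently between a gene and its copies are a candidate explanation. Since the copies are the same for both libraries, this needs a further difference between them, such as in read length or sequence, that the counts do not show.

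Genes of G2 and mitosis were higher in the IR library (median 0.73) in all 24 compared members. Removing the trend over transcript length and GC content left the median at 0.70 (interval 0.50 to 0.93), which argues against that trend as the whole cause. More cycling cells in all phases would also raise genes of S phase. DNA replication genes had a median of 0.0545 with an interval of -0.02 to 0.25, below the interval of 0.51 to 0.98 for the mitosis list. The 5 replication-dependent histone genes had a median of 0.52. Their values of -0.18 to 1.57 overlap the interval of the mitosis list, but with 5 genes this is the range from lowest to highest. Its upper end is Hist1h4d, from 38 and 12 reads. More cycling cells in all phases therefore cannot be told apart from a larger share of cells in G2 or mitosis. The histone range covers both intervals and cannot decide, since it rests on only 5 genes.

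The 15 collagens and other matrix genes had a median log2 ratio of -0.21 in the IR library, with 9 ratios below 1 and 6 above. Col1a1, Col6a3, Fn1 and Col1a2 were lowest and Tnc and Fbn1 highest. The list lay at percentile 1.22 of random lists matched on expression and at 13.025 once these were matched on transcript length and GC content as well. Matching on those properties thus takes the list inside the limits, which does not show that the trend over them is the cause. The median of Col1a1, Col6a3, Fn1 and Col1a2 was -0.91, and -0.78 after that trend was removed. These genes were singled out by their values and decide nothing about the list. Fewer fibroblasts among the cells cannot be told apart from lower expression of these genes, because the fibroblast markers outside the list had a median of -0.30 over 10 genes with an interval of -0.46 to 0.37. The order of the summed fibroblast markers depends on broadly expressed genes, with 5491 CPM in IR against 5020 CPM in NC for all and 2617 against 2792 CPM without Vim and S100a4. The sums of other cell types gave no common direction. Differences in culture density stay untested.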
